A study of Mus musculus with 6 samples.

How the data were processed

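RNA was measured in side population cells of the mouse anterior pituitary, sorted by flow cytometry on Hoechst dye efflux with cells of the highest Sca1 level left out. Per the labels, each sort gave 25000 to 50000 cells, and 1 ng of total RNA was amplified with the NuGEN Ovation Pico whole transcriptome system before Cy3 labelling. Mice carried an inducible diphtheria toxin receptor, either alone (control) or with a growth hormone Cre driver (GHCre), and all received diphtheria toxin at 4 ng per g body weight 2 times a day for 3 or 10 days. The 6 arrays, on 3 slides, fall into 4 groups: control after 3 days (2 arrays), GHCre after 3 days (2 arrays), control after 10 days (1 array) and GHCre after 10 days (1 array). The free-text sample descriptions disagree with the titles for some samples. The titles match the genotype and treatment fields and were used.

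Per the file headers, each array was scanned in 1 colour and quantified with Agilent Feature Extraction 10.7.3.1, and the deposited processed signal is an intensity after background subtraction and detrending, with no scaling between arrays. The deposited series table holds log2 values, which in a comparison with the scanner signal were quantile normalized processed signal for 38017 of the 39429 probes. Its correlation with quantile normalized scanner values was at least 0.9999 in every array. Arrays give no read counts, so their number limits the precision.

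Values were read from the 43020 spots that are not controls. Replicate spots of a probe were averaged on the log2 scale with flagged spots left out, and 32 probe values for which every spot was flagged kept their signal. Each array was then scaled by subtracting the log2 of its 75th percentile. Probes were named through their RefSeq accession (27234 probes) or their own symbol, with current symbols from a reference table used for names alone. Positions are those of the mm9 annotation in the files. Each gene was represented by its probe of highest mean level, and 21072 genes or unnamed transcripts, 16193 of them with a symbol, had that probe well above background on at least 2 of the 6 arrays and were tested. No probe was saturated.

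A linear model with a mean for each of the 4 groups was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, using moderated statistics and Benjamini-Hochberg adjusted p with a threshold of 0.05. The fit has 2 residual degrees of freedom, all from the arrays of 3 days, and a prior of 2.03 degrees of freedom with a standard deviation of 0.556. The contrasts of 10 days assume that the lone arrays vary like those of 3 days. Tested contrasts were GHCre against control after 3 days, the same after 10 days, the difference of these effects, and 10 against 3 days within each genotype. Before the data were examined, the groups, tests, 34 gene lists of cell identity, signalling and cell state, the rule for named genes and the alternatives were set, except those said to be added later. The lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera using an estimated correlation, and with fry. Each list median was also placed among 10000 random lists of matched level. Of 881 list entries, 780 were tested.

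Genes are named by rule. For the comparisons of genotype and their difference these are up to 10 genes in each direction of lowest unadjusted p where none passes the threshold, with a symbol, above background on every array of the brighter group and, after 3 days, with no overlap of the replicates. To these are added up to 4 members of lowest p in each list described, and Gh, Prl, Pomc, Sox2, Ly6a and Abcg2 in every case. Where a gene was not above background on any array of a group, each array of that group was set to no less than its lowest signal above background. The resulting fold is a bound for the reported scaling, no larger than the measured fold, and is written as at least that many fold. It is not a minimum over the alternatives. There the log2 difference fell below the bound, to 1.88 for Mx1, 2.43 for Aqp3, 2.27 for P2rx7 and -2.26 for Ly6k after 3 days, and -0.90 for Hbb-bt after 10 days.

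Tests on simulated data preceded the comparisons. Alternatives were quantile normalization, normexp background correction with an offset of 50 and either scaling, the series table, no filter, a filter requiring signal on all 6 arrays, the mean of all probes, an intensity trend in the variance prior, the replicate number or the slide as a block, and each array of 3 days left out in turn. The list tests of 10 against 3 days within a genotype were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.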

Results

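The data are expression profiles of the stem cell side population of the female mouse anterior pituitary, a fraction sorted for its efflux of Hoechst dye, after diphtheria toxin. Toxin ablates growth hormone cells in GHCre mice, whereas control mice lack the Cre driver. The comparisons ask how the sorted fraction differs between the genotypes 3 and 10 days into the treatment, and whether the difference changes with time. The 75th percentile of signal ran from 186.15 in replicate 1 of the 3 day controls to 298.51 in replicate 1 of the 3 day GHCre group, with 53.8% and 64.4% of probes above background. Correlations across genes between arrays lay between 0.865 and 0.915. The 2 controls of 3 days correlated at 0.865 and the 2 GHCre arrays at 0.906. The p-values of single genes measure only the spread between these samples. Those of camera at the preset correlation compare a list with the other genes. All levels below are log2 signal relative to the array's 75th percentile, and differences are log2 values with the standard error of the fit.

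Gh, the growth hormone transcript of the targeted cells, had levels of 5.69 and 3.65 in the controls and 5.46 and 2.20 in the GHCre arrays after 3 days. After 10 days it stood at 7.86 in the control and 2.21 in the GHCre array. The probe lies on chromosome 11 from 106162492 to 106162735. Its difference was -0.84 ± 1.41 after 3 days (adjusted p = 0.921 with limma) and -5.65 ± 1.99 after 10 days (adjusted p = 1), neither past the threshold, and within slides the 3 day difference was -0.24 and -1.45. Prl, the prolactin transcript, was at 10.3 or higher on all 6 arrays. Pomc, the precursor of corticotropin, ranged from 0.90 to 5.79 and differed by -0.89 ± 1.99 after 3 days, less than the spread between replicates. The 7 somatotrope markers tested had a median of -0.24 after 3 days (adjusted p = 0.599). Abcg2, a Hoechst efflux pump, and Ly6a, which encodes Sca1, differed by 0.14 ± 0.60 and 0.49 ± 0.85. The probe of Sox2, a stem cell factor, was not above background on any array. By mean signal, Prl, Gh and Pomc stood at percentiles 99.997, 96.7 and 93.4 of all genes or unnamed transcripts on the arrays. Which cells of the sorted fraction gave these hormone transcripts was not tested. The GHCre level of 5.46 lies between the control levels, so Gh does not settle the disagreement between the sample descriptions and the titles. Without replicate 1 of the 3 day controls the Gh difference was 0.18, and without replicate 2 of the GHCre group it was 0.78.

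**Figure D1:**
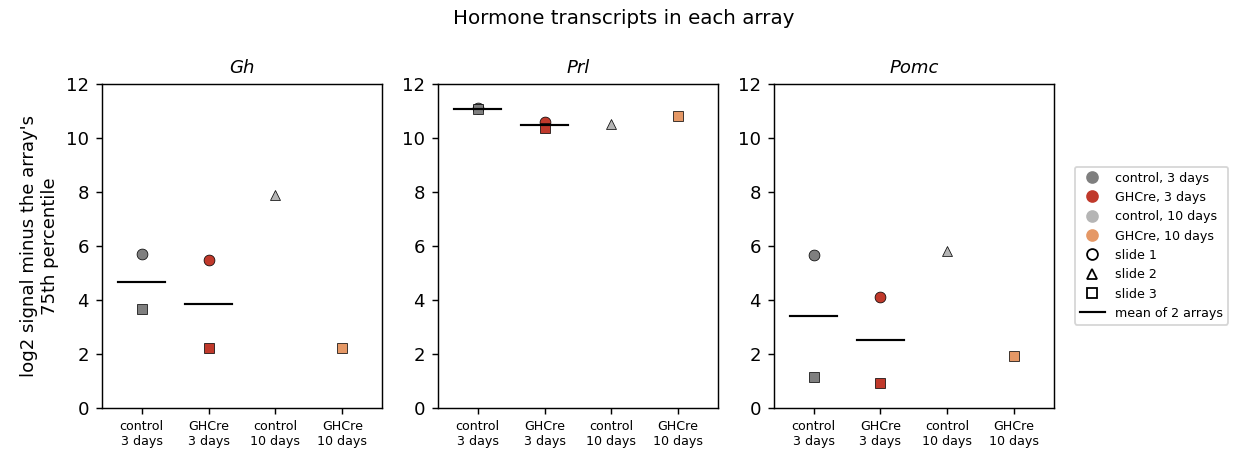
Log2 signal of Gh, Prl and Pomc relative to the 75th percentile of each array (vertical axis), with 1 point per array by group, marker shape for the slide and a line for the mean of 2 arrays. Gh stands at 7.86 in the 10 day control and 2.21 in the 10 day GHCre array.

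After 3 days of toxin, genes of the interferon response and of inflammation were higher in the side population of GHCre mice. Of the 32 interferon genes, which are switched on by interferon signalling, 30 were above the control mean, with a median difference of 1.39. Of the 30 inflammatory cytokines and NF-kB targets, 27 were above it, with a median of 1.48. Both lists rose by limma's camera, with adjusted p = 4.47e-12 and 4.00e-10, and both had adjusted p = 0.354 with an estimated correlation. In simulations the estimated correlation called a log2 shift of 1 in the interferon list in 0% of draws. P-values with an estimated correlation, here and below, therefore cannot decide. At the preset correlation, camera called that list in 47.5% of draws with no shift and a correlation of 0.3 simulated in all lists. The interferon list had an estimate of 0.337 and the inflammatory list 0.034, so the preset p-value of the interferon list overstates its evidence. Within slide 1 and slide 3, which each hold a 3 day array of both genotypes, the interferon median was 1.49 and 1.16 and the inflammatory median 1.33 and 1.47. Lymphocyte markers and fibroblast and pericyte markers moved with these lists, with medians of 1.98 and 0.67, and so did immediate early and dissociation genes (0.42) and, downward, ribosomal protein genes (-0.23). Macrophage and myeloid markers had a median of 0.26 (adjusted p = 0.0634), with 0.53 within slide 1 and 0.88 within slide 3, and from 0.47 to 0.82 when each array of 3 days was left out in turn. They passed in 3 of 16 settings, the mean of all probes (0.37, adjusted p = 0.0156) and normexp with either scaling (0.15 and 0.19). With the 2 interferon genes that were below background in a group set to their bound, the interferon median was 1.39. Both stay above the median at their bound, so it could not move.

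Among interferon genes, Mx1, an antiviral GTPase, was at -5.56 and -6.22 in controls, not above background, and at 0.13 and -0.20 in GHCre mice, at least 14.5-fold higher. Over the alternatives its log2 difference ran from 1.88 to 6.19. Of the oligoadenylate synthetase family, Oasl1 differed by 3.75 ± 0.48 and Oasl2 by 2.19 ± 0.51, and Oas2, with controls not above background, was at least 8.96-fold higher. Mx1 lies on chromosome 16 from 97668644 to 97668703. In this list 10 genes had an unadjusted p under 0.05, 3 passed when adjusted over the list alone (Mx1, Oasl1 and Oas2, of which only Oasl1 was above background in controls), and 0 passed over all genes tested. Among inflammatory genes, the cytokine Il6 was at 1.66 and 1.59 in controls and 4.22 and 4.36 in GHCre mice, a 6.35-fold difference (2.67 ± 0.40, adjusted p = 0.646, chromosome 5 from 30346367 to 30346426). Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, differed by 1.88 ± 0.40, Tnfaip2 by 1.93 ± 0.43 and the cytokine Il11 by 3.43 ± 0.66. In this list 12 genes had an unadjusted p under 0.05, and 0 passed either adjusted over the list alone or over all genes.

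**Figure D2:**
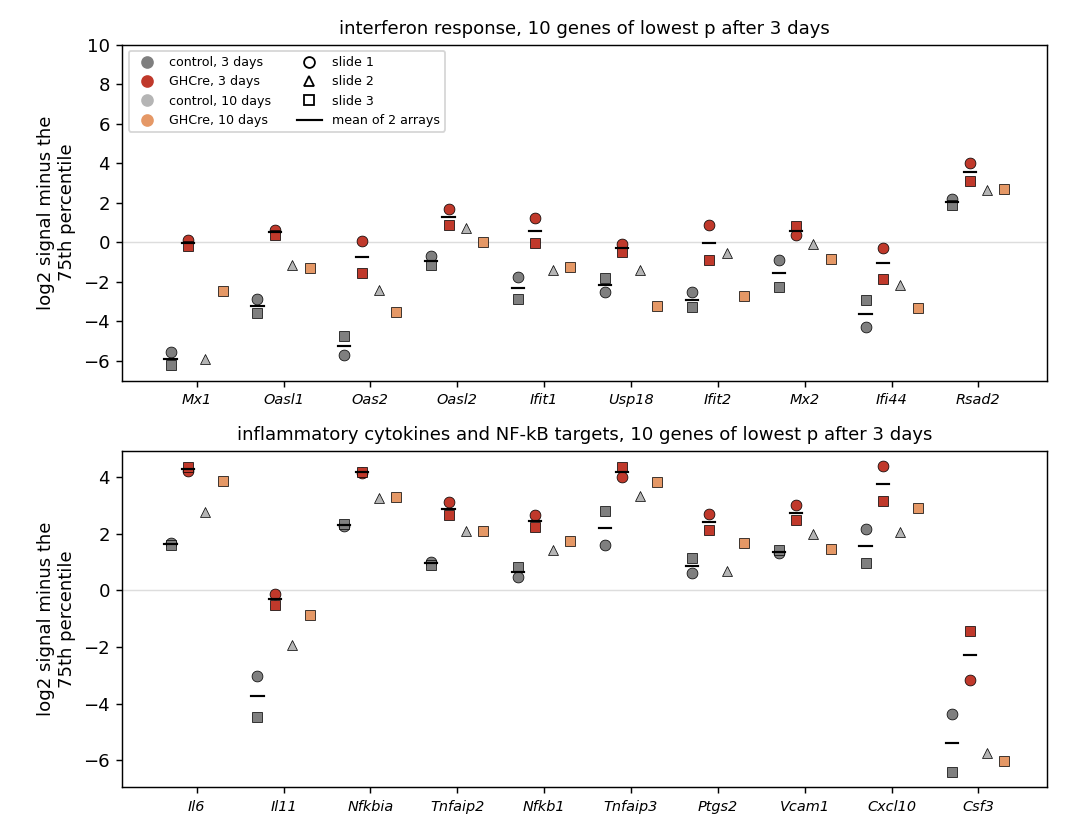
Log2 signal of the 10 interferon and 10 inflammatory genes of lowest p after 3 days relative to the 75th percentile of each array (vertical axis), with 1 point per array by group, marker shape for the slide and a line for the mean of 2 arrays. In the 3 day arrays Il6 stands at 1.66 and 1.59 in controls and at 4.22 and 4.36 in GHCre mice.

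Further lists rose after 3 days by camera. Matrix remodelling genes had 23 of 30 higher and a median of 0.98 (adjusted p = 8.28e-06, within slides 1.06 and 0.69), with Mmp3, a matrix protease, at least 3.02-fold higher and Timp1, a protease inhibitor, at 1.79 ± 0.54. Fibroblast and pericyte markers had 16 of 18 higher (median 0.67, adjusted p = 0.00203), with Des at 2.05 ± 0.49 and Thy1 at 1.74 ± 0.70 (0.98 without replicate 1 of the controls). TGF-beta and BMP pathway genes had 29 of 33 higher (median 0.59, adjusted p = 0.00410), with Bmp7 at least 3.71-fold higher. The receptor Acvr1b was at -3.08 ± 1.07 on its brightest probe (-1.73 without replicate 1 of the GHCre group) and 0.49 on the other. Epithelial-mesenchymal transition genes had 16 of 21 higher (median 0.69, adjusted p = 0.00491), with Foxc2 at 2.17 ± 0.52 and Snai2 at 4.36 ± 1.65 (2.58 without replicate 1 of the controls). Each of these lists had adjusted p = 0.354 with an estimated correlation, and 0 members of each passed adjusted over the list alone. With replicate 1 of the GHCre group left out the medians were 0.65 for matrix remodelling, 0.47 for fibroblast and pericyte markers, 0.36 for TGF-beta and BMP and 0.37 for epithelial-mesenchymal transition, and without replicate 2 of the controls 0.84, 0.43, 0.51 and 0.52. Of these lists, matrix remodelling alone passed in both fits.

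Immediate early genes, which also respond to cell dissociation, had 24 of 27 higher (median 0.42, adjusted p = 0.000794), with Egr3 at 2.59 ± 0.41 and Ier2 at 2.05 ± 0.44. The IL6 family and STAT3 list, which shares 3 genes with the inflammatory list, had 22 of 24 higher (median 0.41, adjusted p = 0.000897), with Bcl6 at 1.28 ± 0.50 and Bcl3 at 1.26 ± 0.49 besides Il6 and Il11. Of 12 lymphocyte markers 10 were higher (median 1.98, adjusted p = 0.00410), with the chemokine receptor Ccr7 at least 5.61-fold higher, while the T cell coreceptors Cd4 and Cd8a had -1.16 ± 0.43 and -2.35 ± 0.82 on their brightest probes and 0.18 and -0.21 on their other probes. The Cd8a value was -1.38 without replicate 1 of the GHCre group. Of 8 folliculostellate markers 5 were higher (median 0.91, adjusted p = 0.0400), with the glutamate transporter Slc1a3 at least 2.75-fold higher, a call lost with the slide as a block (adjusted p = 0.0519). Adjusted p = 0.354 with an estimated correlation held for each of these lists too, and 0 members of each passed adjusted over the list alone. Without replicate 2 of the controls the medians were 0.91 for lymphocyte markers, 0.21 for the IL6 family and STAT3 (adjusted p = 0.231) and 0.55 for folliculostellate markers (adjusted p = 0.312), and the IL6 family and STAT3 median was 0.87 without replicate 1 of the controls and 0.63 without replicate 2 of the GHCre group. The immediate early, IL6 family and folliculostellate calls were lost without replicate 1 of the GHCre group, at 0.30, 0.42 and 1.11.

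A pair of lists fell. Of 18 markers of other hormone and secretory cells 16 were lower (median -0.57, adjusted p = 0.0168, and adjusted p = 0.354 with an estimated correlation), with the prohormone convertase Pcsk2 at -1.29 ± 0.58 (-0.74 without replicate 2 of the controls) and Syt4 at -1.98 ± 1.18. Syt4 depends on single arrays, at -0.42 without replicate 1 and -3.54 without replicate 2 of the GHCre group. Of 75 cytosolic ribosomal protein genes 68 were lower, by a small median of -0.23 (adjusted p = 0.0168, and adjusted p = 0.642 with an estimated correlation), which lay at percentile 49.3 of random lists of matched level. Rpl14 and Rps9 differed by -0.56 ± 0.41 and -0.53 ± 0.42. Both calls were lost without replicate 1 of the controls (medians -0.52 and -0.16) or without replicate 1 of the GHCre group (-0.29 and -0.20), and the ribosomal call also without replicate 2 of the GHCre group (-0.23), where the median of other hormone markers was -0.89. The ribosomal median shrank to -0.079 with quantile normalization (adjusted p = 0.510), -0.081 with normexp and quantile normalization, -0.12 with normexp and the 75th percentile and -0.14 with the series table, none past the threshold. In each of these settings camera called no list lower, so the call of other hormone markers was lost there too. The 21 pituitary stem cell markers had a median of 0.47 (adjusted p = 0.0653). Among them the water channel Aqp3, at least 21.5-fold higher, was the 1 member that passed adjusted over the list alone, with controls not above background. Over 16 settings, immediate early genes passed in 13, and the IL6 family, fibroblast, TGF-beta and epithelial-mesenchymal lists in 12 each. Among these settings the replicate and slide blocks are the same fit after 3 days. Other hormone markers passed in 8, folliculostellate markers in 7 and ribosomal proteins in 6. None of these lists passed with the estimated correlation or fry.

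**Figure D3:**
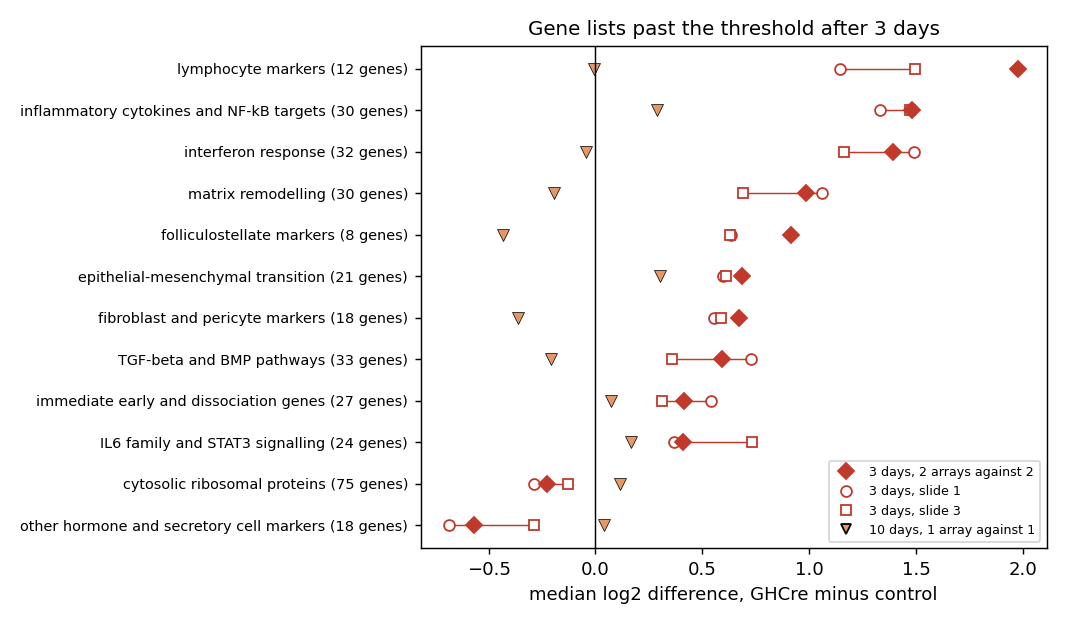
Median log2 difference between GHCre and control mice (horizontal axis) for the 12 lists past the threshold after 3 days (vertical axis), with diamonds for 3 days, open circles and squares for slides 1 and 3 alone, and triangles for 10 days. The interferon list stands at 1.39 after 3 days and -0.05 after 10 days.

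For single genes, 0 of 21072 passed the threshold after 3 days with limma (lowest adjusted p 0.646), and 1390 had an unadjusted p under 0.05, 832 higher and 558 lower, where chance alone gives 1053.6. The matching counts of the other comparisons, given below, were all under 1053.6. The GHCre values lay all above or all below the control values for 7987 genes, 37.9% where chance gives 33.3%. The genes of lowest p, none past the threshold, included P2rx7, an ATP-gated channel, at least 16.6-fold higher with both of its probes higher, Adra2a, an adrenergic receptor, at least 11.4-fold higher, and the acute phase gene Saa2, at least 4.57-fold higher. Ly6k was at least 19.1-fold lower and Dmrta1 at least 8.51-fold lower. Pnma2 and Nemp1, also among these genes, each have 2 probes that disagree in direction. By camera 12 of 34 lists passed, against 0 with an estimated correlation and 0 by fry. Without replicate 1 of the GHCre group 4 lists passed, and without replicate 2 of the controls 7.

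After 10 days, with 1 array in each group, no difference has a replicate check, and lists are described by their medians and percentiles among random lists of matched level. Standard errors take their spread from the arrays of 3 days. The interferon list stood at a median of -0.05 (0.03 with genes below background at their bound, percentile 39.4) and the inflammatory list at 0.29 (percentile 97.9). Mx1 was at -5.91 in the control, not above background, and -2.49 in the GHCre array, and Il6 at 2.77 and 3.87. Transcripts of other hormone cells with lower values in the GHCre array were Cga, the shared subunit of the glycoprotein hormones (-7.23 ± 2.68), Lhb (-3.70 ± 1.89) and Tshb (-3.28 ± 0.85). Ghrhr, the receptor for growth hormone releasing hormone, was at least 19.4-fold lower. The lists they come from had medians of 0.04 for other hormone cells and 0.22 for somatotropes, while their means were -1.01 and -1.17. The Hedgehog pathway, named because its p was the lowest of the lists, had 10 of 13 genes lower and a median of -0.88 (percentile 0.17). The genes of lowest p, none past the threshold, included Golga5 (9.89 ± 0.92), Psmd10 (-8.21 ± 1.10) and Wdr78, at least 59.2-fold lower in the GHCre array.

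With limma 0 genes passed after 10 days, with 638 at an unadjusted p under 0.05, and 0 of 34 lists passed by camera, by camera with an estimated correlation or by fry. With an intensity trend in the variance prior 2 lists passed, and without replicate 1 or replicate 2 of the 3 day GHCre group 1 list did. These counts assume that each lone array varies like those of 3 days. Leaving out either 3 day GHCre array gives the same fit for this comparison, with all residuals from the 3 day controls. The 10 day control is alone on its slide, so slide and genotype cannot be told apart there.

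Set against the 3 day arrays, the 1 GHCre and 1 control array of 10 days gave a lower GHCre effect on the interferon list, with 28 of 32 genes lower and a median of -1.30 (adjusted p = 9.30e-07 by camera on the difference itself). All spread between arrays in this test comes from the 3 day arrays, so its p-values hold only if the lone arrays vary like them. They also assume a correlation of 0.01 between the genes of a list, where the interferon list had an estimate of 0.337. The arrays cannot show a change with time beyond these 2 samples. For the inflammatory list 25 of 30 genes were lower (median -1.48, adjusted p = 0.000301), and for matrix remodelling 23 of 30 (median -1.21, adjusted p = 0.000301). Fibroblast and pericyte markers had 15 of 18 lower (median -0.98, adjusted p = 0.000804), and pituitary stem cell markers 17 of 21 (median -0.91, adjusted p = 0.0160). These 5 lists each had adjusted p = 0.422 with an estimated correlation. Ribosomal protein genes were higher, with 70 of 75 in that direction (median 0.33, adjusted p = 0.00929, and adjusted p = 0.707 with an estimated correlation). Among members, the difference was -3.90 ± 0.83 for Oasl1, -3.70 ± 0.85 for Usp18, -1.83 ± 0.69 for Nfkbia and -3.51 ± 0.85 for Des. With genes below background at their bound the interferon median was -1.13. The matrix, fibroblast, stem cell and ribosomal calls were lost without replicate 1 of the 3 day GHCre group (medians -1.05, -0.67, -0.50 and 0.31), and the inflammatory median was -0.88 without replicate 2 of the 3 day controls. The stem cell call was also lost without that control (-0.55), and the ribosomal call without replicate 1 of the controls (0.27) or replicate 2 of the GHCre group (0.36). Over all settings the ribosomal median ranged from 0.18 to 0.38.

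With limma 0 genes passed in this test of the difference, with 835 at an unadjusted p under 0.05, and 12 lists passed by camera, against 0 with an estimated correlation and 0 by fry. Without replicate 1 of the 3 day GHCre group 3 lists passed, and without replicate 2 of the 3 day controls 6. Across genes the differences after 3 and 10 days had a Pearson correlation of 0.017 and a Spearman correlation of 0.034, with 51.4% of genes of the same sign, and genes are not independent replicates.

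Within GHCre mice, 0 genes differed between 10 and 3 days with limma, and 849 had an unadjusted p under 0.05. Within control mice, the background for time, these counts were 0 and 855. Each 10 day side here is 1 array, so these tests too take their spread between arrays from the 3 day arrays. The counts of lists given below also move with the scaling and with the slide as a block. The interferon list was lower in the 1 GHCre array of 10 days (median -1.27, 27 of 32 genes, adjusted p = 2.96e-08, and adjusted p = 0.474 with an estimated correlation). In the 1 control array it stood at a median of 0.60 (adjusted p = 0.216). By camera 12 lists passed in GHCre mice and 2 in controls, against 0 and 0 with an estimated correlation and 0 and 2 by fry. In controls the 2 lists of camera (erythroid markers and ribosomal proteins) are not those of fry (somatotrope markers, adjusted p = 0.0160, and the Wnt pathway, adjusted p = 0.0318). Without replicate 1 of the 3 day GHCre group 3 lists passed in GHCre mice, and without replicate 1 of the 3 day controls 0 passed in controls.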

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

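The test of myeloid transcripts, with its rule that the interval and not the value must clear the bound, and the list tests of time within a genotype were chosen only after the results were seen. The 12 lists given in the second pattern and the last paragraph were singled out because their GHCre effect differed between 10 and 3 days in a test of that difference. That test had 1 array per genotype at 10 days and took all spread between arrays from the 3 day arrays. All 12 lost their call with an estimated correlation. That loss decides nothing, since in simulations of the 3 day comparison the test called a log2 shift of 1 in 0% of draws. The patterns of the 3 day lists and of single-gene size were chosen for weighing without such a rule.

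The first pattern is the higher interferon and inflammatory lists in GHCre mice after 3 days, medians 1.39 and 1.48. The rise was also present without the dimmer control array, at an interferon median of 1.16 in the other pair of arrays. Its 95% bootstrap interval over genes, 0.79 to 1.73, lies above the bound of 0.5 set beforehand. That argues against the dimmer array as the sole source in these samples. The interval treats genes of 1 pair of arrays as independent, so it holds no spread between arrays and excludes no other array effect. More myeloid cells in the sort may contribute and stay open. The 7 abundant myeloid transcripts had a median of 0.71, just over the bound of 0.70, in an interval from -0.26 to 1.31 that spans it. They were C1qc at 4.72, Cd74 at 1.31, Tyrobp at 0.95, Fcer1g at 0.71, Lyz2 at 0.20, C1qb at -0.26 and Ctss at -0.27. Of the 3 splits of the 4 arrays, 1 gave an interferon median as large, the real one at 1.39, and the highest other reached 0.51 in size, but 3 splits are too few for a share under 0.05. Lymphocyte markers rose too (10 of 12 higher, median 1.98), as did fibroblast and pericyte markers (16 of 18 higher, median 0.67). Whether more such cells were sorted was not tested. Ablation of growth hormone cells, the biological difference that the design names, and cell dissociation, since immediate early and dissociation genes also rose (median 0.42), remain open and untested.

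The second pattern is a lower interferon effect in the 2 single arrays of 10 days than after 3 days, a median of -1.30. All spread between arrays comes from the 3 day arrays, so chance in the 10 day arrays is not excluded. A 10 day control that already holds a higher level could contribute: its interferon genes were above the 3 day controls by a median of 0.60, with an interval from -0.04 to 0.90 that spans the bound of 0.70. The 10 day control sits alone on its slide, so the 10 day median of -0.046 and the slide cannot be told apart. Duration of ablation remains open and untested.

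The third pattern is the size of single-gene differences, such as 9.89 for Golga5 after 10 days. Uneven amplification of scarce transcripts from 1 ng of RNA is a candidate explanation: pairs of arrays of different groups held on average 426.08 genes apart by 16-fold or more, against 498.5 in the 2 pairs of 1 group, a ratio of 0.85 where a bound of 1.5 was set. Those 2 pairs differ, at 678 genes for the controls and 319 for GHCre, so the ratio is 1.12 without replicate 1 of the controls and ranges from 0.57 to 1.33 when each array of 3 days is left out. Differences between mice of 1 group enter these counts too. No biological explanation was tested for this pattern.

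The other lists whose GHCre effect differed between 10 and 3 days are given as medians of the difference. Over all 12 lists, the adjusted p ran from 9.30e-07 to 0.0472, and from 0.422 to 0.707 with an estimated correlation. It was -1.48 for inflammatory cytokines and NF-kB targets, -1.21 for matrix remodelling and -0.98 for fibroblast and pericyte markers. It was -0.91 for pituitary stem cell markers, -0.88 for TGF-beta and BMP pathways and -0.74 for folliculostellate markers. It was -0.70 for the Hippo and YAP pathway, -0.63 for the Hedgehog pathway and -0.54 for FGF and EGF pathways. It was -1.43 for erythroid markers and 0.33 for cytosolic ribosomal proteins. Of the 12 calls, 9 were lost without replicate 1 of the 3 day GHCre group, without replicate 2 of the 3 day controls 6, without replicate 1 of those controls 3 and without replicate 2 of that GHCre group 2. The erythroid median ranged from -2.69 to -0.31 and the Hedgehog median from -1.92 to -0.40 over the settings run. Moves of over 1.5 times also came without replicate 2 of the 3 day controls, to -0.88 for inflammatory cytokines, -0.55 for stem cell markers, -0.42 for Hippo (adjusted p = 0.452) and -0.30 for FGF and EGF (adjusted p = 0.383). The stem cell median was -0.50 without replicate 1 of the 3 day GHCre group, and the folliculostellate median -1.29 without replicate 1 of the 3 day controls. Interferon and inflammatory lists passed in 13 of 15 settings, fibroblast, TGF-beta and matrix lists in 12, and stem cell and folliculostellate markers in 11. Hippo passed in 9, ribosomal proteins in 8, FGF and EGF in 7, Hedgehog in 5 and erythroid markers in 4 of 14. None of these lists passed with the estimated correlation or fry.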

How the results depend on the processing

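In simulations of the 3 day comparison, limma called 0% of genes changed by 16-fold, with 97.1% at an unadjusted p under 0.05, so a count of 0 genes excludes no change of that size. For lists, camera at the preset correlation called the interferon list in 100% of draws with a log2 shift of 1 and no correlation. With no shift and a correlation of 0.3 simulated in all 34 lists at once, it called that list in 47.5% of draws and on average 9.675 of the others. With 0.1 in all lists it called that list in 10% of draws and on average 2.3 of the others. With 0.05 these values were 0% and 0.65. The correlation estimated for the interferon list was 0.337, and 0.034 for the inflammatory list. With a log2 shift of 1, the estimated correlation called the interferon list in 0% of draws and fry in 2.5% to 10%, so neither decides. Dim transcripts limit all fits: 53.8% to 65.7% of probes were above background.

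The count of genes past the threshold was 0 in all comparisons and settings run. Among 154 results, each a gene or a list in 1 comparison, 1905 of 2121 values kept their direction and side of the threshold. Of the rest, 194 lost the threshold, 11 gained it and 11 reversed. Since no gene passed in any setting, genes could only keep or reverse, and every loss and gain is of a list. The share of values kept is therefore no measure of how stable the list calls are. The interferon, inflammatory, matrix remodelling and lymphocyte lists passed after 3 days in 14 of 16 settings each, all by camera at the preset correlation. The 2 others, estimated correlation and fry, gave no call. These 16 settings are not all distinct. After 3 days the replicate and slide blocks are the same fit, and the series table holds quantile normalized signal. Medians ran from 0.94 to 1.90 for interferon, 1.03 to 1.60 for inflammatory and 0.91 to the reported 1.98 for lymphocyte lists. Normexp with the 75th percentile moved the median of all genes after 3 days to -0.16 and in the difference to 0.14, and the reported scaling left it at 0.11 for GHCre mice over time.

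The counts of lists that follow moved by over 1.5 times, and the cause was not tested beyond the smaller number of arrays where 1 was left out. An estimated correlation gave 0 lists after 3 days, in the difference and over time in either genotype. Fry gave 0 in these except controls over time. GHCre mice over time had 12 lists in the reported fit, 7 with quantile normalization, 7 with the series table and 4 with the slide block. Controls over time had 2, with 0 under quantile normalization, 0 with the series table, 9 with normexp and the 75th percentile, 7 with normexp and quantile normalization and 1 with signal required on all 6 arrays. After 10 days 2 lists passed with an intensity trend. Leaving out each array of 3 days in turn gave 4 to 15 lists after 3 days, 0 to 1 after 10 days, 3 to 12 in the difference, 3 to 12 in GHCre mice over time and 0 to 2 in controls over time, and a correlation of the 3 and 10 day differences from -0.020 to 0.046.

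Reversals occurred as follows, and the cause was not tested. With 1 array left out, the 3 day difference ranged from -2.47 to 0.78 for Gh, -3.15 to 1.37 for Pomc, -0.33 to 0.62 for Abcg2 and -0.55 to 1.52 for Ly6a, and the somatotrope median from -0.26 to 0.17. The Hedgehog median of GHCre mice over time ranged from -0.85 to 0.16 with 1 array left out, and was 0.11 with signal required on all 6 arrays. Over all settings it ranged from -1.20 to 0.16. With that filter the macrophage and myeloid median after 3 days was -0.0065. The interferon median after 10 days was 0.022 with normexp and the 75th percentile and 0.038 with normexp and quantile normalization.

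The replicate numbers are not shown to pair the samples (correlation of replicate differences 0.087). With the replicate number as a block 13 lists passed after 3 days and 16 in the difference, and after 3 days 0 genes did, with 1473 at an unadjusted p under 0.05. For the 3 day comparison this block is the slide. Slide as a block gave values only after 3 days and for GHCre mice over time. Leaving out saturated probes was not run, since no probe was saturated.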

Other observations

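The list tests of time within a genotype were chosen only after the data were seen. Each 10 day group is 1 array, with the control alone on its slide, and the tests take all spread between arrays from the 3 day arrays. In the control array of 10 days 6 of 6 erythroid markers were higher than after 3 days, with a median of 1.95 (adjusted p = 0.00915 by camera, and adjusted p = 0.733 with an estimated correlation), and 72 of 75 ribosomal protein genes were lower (median -0.26, adjusted p = 0.000399, and adjusted p = 0.733 with an estimated correlation). Without replicate 1 of the 3 day controls 0 lists passed in this comparison, with medians of 2.14 and -0.19, and without replicate 2 of them the erythroid median was 1.60 (adjusted p = 0.239). The erythroid call passed in 7 of 14 settings, with medians from 1.04 to 2.14, and the ribosomal call in 10 of 15, with medians from -0.33 to -0.12. The GHCre effect on erythroid markers had a median of 0.78 after 3 days (adjusted p = 0.0641) and -0.90 after 10 days, where Hbb-bt, a beta globin gene, was at least 4.40-fold lower in the GHCre array than in the control array. In the GHCre array of 10 days the markers of the posterior and intermediate lobe were higher than after 3 days in 7 of 7 genes (median 0.77, adjusted p = 0.0479), as were neutrophil markers in 7 of 7 (median 0.55, adjusted p = 0.0379), each with adjusted p = 0.474 with an estimated correlation. Of 16 alternatives, the lobe markers passed in 7 and the neutrophil markers in 3, and neither passed with quantile normalization, normexp, the series table, signal required on all 6 arrays or the slide as a block (adjusted p = 0.251 and 0.174). Their medians were 0.24 and 0.31 without replicate 1 of the 3 day GHCre group, and the lobe median was 1.31 without replicate 2 of it.

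Cell division genes showed no call in the genotype comparisons. After 3 days G2 and M phase genes had a median of -0.05 (adjusted p = 0.532) and S phase genes 0.15 (adjusted p = 0.585), with means of 0.28 and -0.01. The camera direction was up for both, so median, mean and test differ in sign for each list. Genes of p53 and apoptosis had a median of 0.52, with 19 of 27 higher (adjusted p = 0.0641). In the Hedgehog pathway, the pathway's target Gli1 was at -1.72 and -0.47 in the 3 day controls, 1.55 and 0.68 in the 3 day GHCre arrays, 0.24 in the 10 day control and -2.63 in the 10 day GHCre array. The other Gli1 probe differed by only 0.61 after 3 days, when 8 of the 13 Hedgehog genes were lower (median -0.19). Hhip, another Hedgehog target, differed by -2.78 ± 0.74 after 10 days, not past the threshold.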
